A study of Mus musculus with 12 samples.

How the data were processed

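Total RNA was extracted with Trizol from prefrontal cortex of female mice, ribosomal RNA was depleted, and libraries made with the KAPA RNA HyperPrep kit were sequenced on an Illumina NovaSeq, per the labels. The authors quantified transcripts with Salmon 1.4.0, and their notes also name DESeq2 1.30.1 and the mouse build GRCm38, per the submitters' processing notes. The deposited files hold, for each transcript, an estimated count of reads, which need not be whole, a TPM value, a length and an effective length, per the file headers. The strand and bias settings of the quantification and the annotation release were not given in the sources used here. Reads of genes that overlap on opposite strands or share near-identical copies may therefore have been divided in ways that cannot be seen here.

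Each file lists 113911 transcripts. Of these, 113694 were matched to 35272 genes, 21899 of them protein coding, through their identifiers in the GENCODE M21 annotation, which also gave coordinates. The other 217 transcripts, with 0.079 to 0.099% of the estimated reads of a library, were left out. Estimated counts were summed per gene and rounded to whole numbers. The deposited TPM and effective lengths served for length-scaled counts, which thus take in each library's effective lengths, while the sums do not. Effective length was above length for 13.7 to 17.0% of the transcripts of a library. CPM were computed with TMM library sizes.

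Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr kept 16796 genes, libraries were scaled by TMM, and the quasi-likelihood test with robust dispersion was fitted to all 12 libraries with 1 coefficient for each of the 4 groups, which left 8 residual degrees of freedom. The common biological coefficient of variation was 11.1%. Contrasts were old against young under saline, morphine against saline in young and in old mice, the difference of these morphine effects, and old against young under morphine. Benjamini-Hochberg adjustment was applied over all genes of a comparison with a threshold of 0.05. Against 3 libraries per group, an exact permutation test of a single gene cannot give a two-sided p under 0.1.

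The comparisons, the rule for naming genes and 42 gene lists were fixed before the data were examined. The lists were tested with camera (limma 3.58.1) at an inter-gene correlation of 0.01 on log2 CPM with a prior count of 2, and again with the correlation estimated for each list and with fry, each adjusted over the lists of a comparison. Of 67 calls over the 5 comparisons with the preset correlation, 2 held with an estimated correlation, both for the clustered protocadherins. Genes named are the 8 largest rises and the 8 largest falls among genes past the threshold with a name of their own, a mean of at least 1 CPM and no overlap between the groups, up to 4 members with the smallest p of each list called or holding a called gene, the 10 genes with the smallest p where fewer than 8 passed, and 6 genes in every comparison. Gene models without a name of their own, such as those with a Gm number or a Rik identifier, were counted but not named. A gene that met this rule is not reported here.

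Replicates of a group were compared before averaging: the chi-square per degree of freedom of every pair was between 5.17 and 24.73, so none were copies of 1 library. Young morphine replicate 2 had 148856113 estimated reads and the others 20236452 to 40480571. Counting 3 reads as a floor, this corresponds to 0.02 CPM in the deepest library and 0.148 CPM in old morphine replicate 2, for counting error only.

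Alternatives were other scalings (DESeq2 size factors, upper quartile), no filter or a stricter filter on low counts, DESeq2 1.42.0, limma-voom, length-scaled counts, protein-coding genes alone, only the libraries compared, the replicate number as a block, 1 surrogate variable (sva 3.50.0), scores of myelin or striatal markers in the model, and leaving out each library. Alternatives added after the data were seen were a natural spline of GC share and length with 5 degrees of freedom each removed from each library, alone or with the block or a score of olfactory bulb markers, that score alone, young morphine replicate 2 thinned to the median of the others, and the mean morphine effect of both ages. The tests were checked on simulated counts with known changes, put into 200 genes above a low level. Counts were drawn independently for each gene from its fitted spread. Shifts that many genes share in a library, such as tissue makeup, were thus left out, and GC and length trends were included only where stated. With no change and no trend simulated, edgeR made 0 or 1 calls per comparison and DESeq2 made 2 to 10. With no change but the observed GC and length trends simulated, edgeR made 104 calls for age under morphine and 0 in each other comparison. With the trend removed from those counts it made 1 call for age under morphine.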

Results

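RNA abundance was measured in prefrontal cortex of female C57BL/6JN mice, an inbred strain, at 4 months of age (young) and at 20 months (old), after an intraperitoneal injection of saline or of morphine at 3 mg/kg. Morphine is an opioid analgesic that acts mainly through the mu opioid receptor. The 12 libraries formed 4 groups of 3: young saline, young morphine, old saline and old morphine. The time from injection to tissue collection was not given in the sources used here. Libraries held 20236452 to 40480571 estimated reads, except young morphine replicate 2, which held 148856113, 4.31 times the median of the others. Levels are given as CPM (read counts scaled to a common library total) ± SD with n = 3 per group, and log2 fold changes ± SE come from 1 edgeR quasi-likelihood fit of 16796 genes, with Benjamini-Hochberg adjusted p. The SE was derived as the size of the log2 fold change divided by the square root of the test's F statistic. The labels do not say whether replicates were separate animals, so p-values measure the spread between these samples. The study's title names the question, which is how the cortical response to morphine depends on age.

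Age under saline. The clustered protocadherins, cell-surface adhesion proteins by which neurons tell their own branches from others, were higher in old than in young saline mice, and Gpr17, Marcksl1 and Sox11 were among the genes that were lower. Pcdhga2 (chromosome 18, 37668953 to 37841870, GRCm38) rose from 18.0 ± 1.92 to 35.2 ± 1.45 CPM, a log2 fold change of 0.97 ± 0.10 with adjusted p = 0.000258. Gpr17 (chromosome 18, 31942997 to 31949636), a receptor of oligodendrocytes at the start of differentiation, fell from 40.1 ± 2.43 to 25 ± 0.421 CPM, a log2 fold change of -0.68 ± 0.07 with adjusted p = 0.000258. Marcksl1 (chromosome 4, 129513581 to 129515985), an actin-binding protein of growing processes, fell by 0.82 on the log2 scale, and Sox11, a transcription factor of immature neurons, fell by 0.42. Gpr17 was the 1 of 16 oligodendrocyte precursor genes that fell (adjusted p = 0.0335 for the list by camera, and adjusted p = 0.339 with an estimated correlation), and Sox11 the 1 of 12 immature neuron genes, a list that did not pass camera (adjusted p = 0.998). The immunoglobulin genes Igkc and Ighm rose, with Igkc at 0.451 ± 0.158 CPM in young and 5.30 ± 1.68 CPM in old mice.

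In total, 78 of 16796 genes passed an adjusted p of 0.05, 40 higher and 38 lower in old mice, with a median change of 0.56 on the log2 scale. Unadjusted p was under 0.05 for 2275 genes, where chance gives 840, and 18.1% of genes had no overlap between the groups, where chance gives 10%. The largest rises that met the naming rule were Igkc (log2 fold change 3.50), the pseudogene Nlrp5-ps (2.16), Exoc3l4 (1.78), the vomeronasal receptor gene Vmn1r90 (1.65), the calcium-binding protein gene Cabp7 (1.4), Casp1 (1.31), which encodes an inflammatory caspase, Ighm (1.20) and Grid2ip (1.11). Nlrp5-ps (chromosome 7, 14530652 to 14622479) rose from 7.70 ± 0.999 to 34.3 ± 4.29 CPM with adjusted p = 4.57e-05. The largest falls were Marcksl1, Kcng1 (-0.81), a potassium channel subunit, Tnnc1 (-0.80), a troponin, Nrep (-0.76), Gpr17, Car8 (-0.63), Lypd1 (-0.58) and Tmem200c (-0.57). Reads of Nlrp5-ps, Vmn1r90, the immunoglobulin genes, the MHC genes and the protocadherins can be shared with near-identical copies, and their values are uncertain to that extent.

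Of 57 measured clustered protocadherins, 6 rose and 0 fell, and 23 rose and 2 fell when adjusted over the list alone, with a median log2 fold change of 0.21. Pcdhb14, Pcdhb9 and Pcdhb5 rose by 0.66, 0.79 and 0.64. The list passed camera with adjusted p = 5.64e-10, and also with an estimated correlation, where adjusted p = 0.0308. It was the 1 list of 42 in this comparison that did.

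Immune lists were higher by camera with its preset correlation. Of 25 interferon-stimulated genes, 1 rose (Ifi27, 0.73) and 8 rose when adjusted over the list alone, with a median of 0.38 (adjusted p = 5.1e-09, and adjusted p = 0.339 with an estimated correlation). Of 17 genes of MHC class I antigen presentation, 1 rose (H2-T22, 0.41) and 9 rose when adjusted over the list alone (adjusted p = 1.7e-07, and adjusted p = 0.339 with an estimated correlation). Activated microglia genes had a median of 0.38 and reactive astrocyte genes a median of 0.37 with 0 members past the threshold over all genes, and adjusted p = 0.339 for each with an estimated correlation. Of 12 genes of lymphocytes and MHC class II, 1 rose (Ighm), with a median of 0.92 (adjusted p = 7.8e-05, and adjusted p = 0.339 with an estimated correlation). All 12 measured blood cell markers stood higher in old saline mice, with a median of 1.41, 0 members past the threshold over all genes and 4 when adjusted over the list alone (adjusted p = 8.54e-05, and adjusted p = 0.466 with an estimated correlation). C4b, a complement gene, had a log2 fold change of 1.34 with adjusted p = 0.11. Among 23 myelin markers, Anln (1.10) and Trf (0.64), the iron carrier transferrin, rose, with adjusted p = 0.539 for the list with an estimated correlation. Chrm1, the M1 muscarinic receptor, fell by 0.27.

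The count was 389 by DESeq2 and 62 by limma-voom, and leaving out young saline replicates 1, 2 or 3 gave 29, 33 and 15, and old saline replicates 1, 2 or 3 gave 119, 23 and 28. Olfactory bulb markers were high in old saline replicates 1 and 2, and the median of that list was 1.97 higher in old saline mice, with adjusted p = 0.614 with an estimated correlation; with the score of these markers in the model 28 genes passed.

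**Figure D1:**
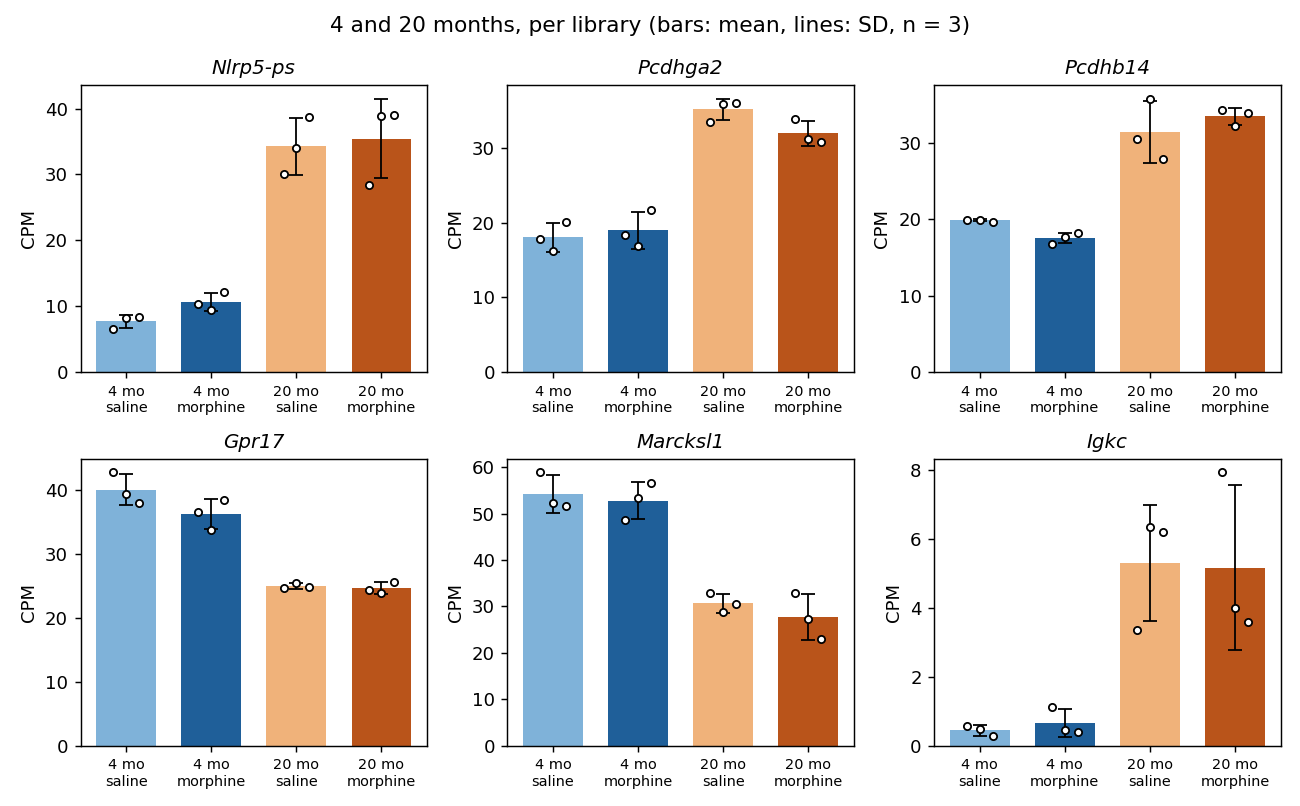
CPM (vertical axes) of Nlrp5-ps, Pcdhga2, Pcdhb14, Gpr17, Marcksl1 and Igkc in the 4 groups, with points for the 3 libraries of a group, bars for their mean and lines for 1 SD. Pcdhga2 stood at 18.0 CPM in young saline and 35.2 CPM in old saline mice, and Gpr17 at 40.1 and 25 CPM.

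Morphine in old mice. Egr2, Arc and Fos, which belong to the immediate early genes that neurons switch on within minutes of activity, were higher after morphine than after saline in old mice. Egr2 (chromosome 10, 67535475 to 67542188), an activity-induced transcription factor, rose from 2.08 ± 0.0665 to 8.84 ± 1.36 CPM, a log2 fold change of 2.08 ± 0.19 with adjusted p = 0.000372. Arc (chromosome 15, 74669083 to 74672570), a regulator of synaptic glutamate receptors, rose from 46.4 ± 12.3 to 171 ± 25.8 CPM (1.88 ± 0.23, adjusted p = 0.0174), and Fos (chromosome 12, 85473890 to 85477273) rose from 5.01 ± 1.37 to 14.9 ± 2.10 CPM (1.57 ± 0.25, adjusted p = 0.0222). The chaperone genes Hspa5 and Hsp90b1 and the clock genes Per2, Bhlhe40 and Per1 rose too, and the glucocorticoid-responsive genes Fkbp5 and Hif3a fell.

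Altogether 98 genes passed, 79 higher and 19 lower with morphine, a share of 80.6% higher; with upper-quartile scaling 87 passed and the share was 67.8%. Unadjusted p was under 0.05 for 3133 genes, and 20.4% of genes had no overlap between the groups against 10% by chance. Of 29 immediate early genes, 9 rose and 0 fell, and 17 rose when adjusted over the list alone, with a median of 0.53 (adjusted p = 5.72e-10 by camera, and adjusted p = 0.521 with an estimated correlation). They included Nr4a1 (1.13), a nuclear receptor, Dusp6 (0.86), a phosphatase of ERK kinases, and Ier5 (0.66). Outside that list, Dusp5 (0.92), Klf10 (1.01) and Serinc2 (1.34) rose. Of 20 genes of the unfolded protein response, the chaperones Hspa5 (0.49) and Hsp90b1 (0.33) rose and 13 rose when adjusted over the list alone (adjusted p = 1.31e-08, and adjusted p = 0.521 with an estimated correlation). Of 18 circadian clock genes, Per2 (0.72), Bhlhe40 (0.56) and Per1 (0.38) rose (adjusted p = 0.00423, and adjusted p = 0.521 with an estimated correlation). These 3 lists passed fry, each with adjusted p = 0.0118, which tests a list on its own and not against other genes. Among 18 cytosolic heat shock chaperones, Chordc1 rose by 0.41 (adjusted p = 0.638 for the list with an estimated correlation).

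The falls that met the naming rule were Hif3a (-1.01), a hypoxia-inducible factor subunit, Acacb (-0.76), an acetyl-CoA carboxylase, Sh2d3c (-0.64), Cmtm3 (-0.60), Dact2 (-0.58), Prodh (-0.56), proline dehydrogenase, Pgap2 (-0.56) and Tpst2 (-0.54). Of 26 glucocorticoid-responsive genes, Hif3a and Fkbp5 (-0.49), a co-chaperone of the glucocorticoid receptor, fell and Per1 rose, and 11 fell and 1 rose when adjusted over the list alone (adjusted p = 5.15e-05, and adjusted p = 0.532 with an estimated correlation). Markers of astrocytes (median -0.21) and microglia (median -0.25) were lower by camera, with 9 members of each past the threshold when adjusted over the list alone and 0 over all genes (adjusted p = 0.68 for each with an estimated correlation). Other non-neuronal lists were lower by camera as well, with 0 members past the threshold over all genes: markers of meningeal fibroblasts (median -0.71, 16 of 16 negative), collagens (-0.35, 15 of 16), mural cells (-0.30, 11 of 12) and endothelium (-0.22, 13 of 17), with adjusted p = 0.68 for each with an estimated correlation. Also lower by camera were reactive astrocyte genes (median -0.42, adjusted p = 0.0011) and interferon-stimulated genes (-0.27, adjusted p = 0.000294). So were activated microglia (-0.21, adjusted p = 0.00556), MHC class I (-0.21, adjusted p = 0.0126) and inflammatory genes (-0.16, adjusted p = 0.0286). With an estimated correlation 0 lists passed in this comparison (smallest adjusted p = 0.521). Myelin markers were higher by camera with a median of 0.24 (adjusted p = 0.0194, and adjusted p = 0.68 with an estimated correlation). Their mean log2 CPM was 4.08 ± 0.11 in old saline and 4.26 ± 0.13 in old morphine mice, and with that mean in the model 28 genes passed. The ribosomal protein gene Rpl10a fell by 0.43.

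By DESeq2 776 genes passed and by limma-voom 66, and with length-scaled counts 30. The changes moved with the GC share of the genes' transcripts (Spearman rho -0.47 over 13399 genes, against 0.21 in young mice and -0.56 for the difference of the effects). With a smooth trend of each library on GC share and length removed, 88 genes passed, 54 of them among the 98; all 98 kept their sign with an unadjusted p under 0.05, and their median change went from 0.41 to 0.35 with an SE of 0.07 in both. The count was 711 without old saline replicate 1, 276 without old morphine replicate 1, 196 without young saline replicate 1, 63 without young morphine replicate 1 or 3, 61 without young morphine replicate 2, 14 without old morphine replicate 2 or 3 and 10 without old saline replicate 2 or 3, and 7 genes passed in all 12 of these fits: Trib2, Spry4, Pfkfb3, Bhlhe40, Dusp4, Egr2 and Sh2d3c.

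**Figure D2:**
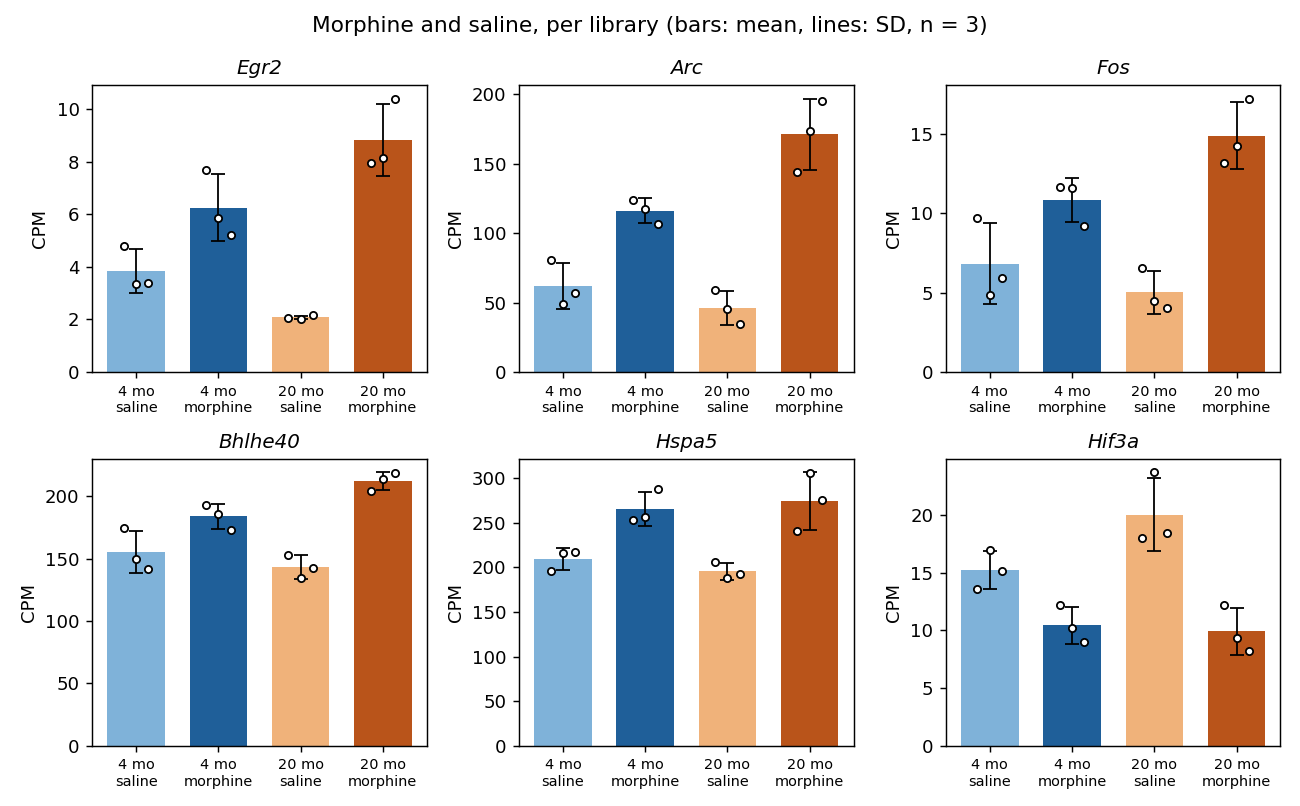
CPM (vertical axes) of Egr2, Arc, Fos, Bhlhe40, Hspa5 and Hif3a in the 4 groups, with points for the 3 libraries of a group, bars for their mean and lines for 1 SD. In old mice Arc stood at 46.4 CPM after saline and 171 CPM after morphine, and in young mice at 62.1 and 116 CPM.

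Morphine in young mice. No gene passed in young mice, where edgeR's smallest adjusted p was 0.0625 and unadjusted p was under 0.05 for 1530 genes against 840 by chance. The genes with the smallest p were Inf2 (0.47 ± 0.07), an actin-regulating formin, Serinc2 (1.54 ± 0.24) and Nyap2 (-0.39 ± 0.06), each with adjusted p = 0.0625, followed by Cntn2 (0.48), an axonal adhesion protein, with adjusted p = 0.101. Arc stood at 62.1 ± 16.5 CPM after saline and 116 ± 8.96 CPM after morphine (0.90, adjusted p = 0.28), and Fos at 6.81 ± 2.55 and 10.8 ± 1.38 CPM (0.66, adjusted p = 0.429). Oprm1, the mu opioid receptor gene, had a log2 fold change of 0.53 with adjusted p = 0.532. By DESeq2 164 genes passed and by limma-voom 2.

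By camera, immediate early genes (median 0.24, 7 of 29 past the threshold when adjusted over the list alone) and unfolded protein response genes (median 0.18, 11 of 20 when adjusted over the list alone) were higher, with adjusted p = 0.798 and adjusted p = 0.755 with an estimated correlation. Myelin markers had the smallest camera p, with a median of 0.49 and 11 of 23 past the threshold when adjusted over the list alone (adjusted p = 1.28e-10, and adjusted p = 0.755 with an estimated correlation). Their mean log2 CPM was 3.80 ± 0.24 in young saline and 4.21 ± 0.12 in young morphine mice. Astrocyte markers (median -0.17) and mitochondrially encoded genes (median -0.40) were lower by camera, with adjusted p = 0.798 for each with an estimated correlation, and the mitochondrially encoded genes had a median of -0.26 with the GC and length trend removed. Without young saline replicate 1, 67 genes passed, and without old saline replicate 1, 6 passed. At this size of group, the test recovered 22.4% of the smallest simulated changes (under 1.5-fold), 70.1% at 1.5-fold and 89.4% at 2-fold in this comparison. The simulated genes varied independently, so these shares need not hold for the real libraries.

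The difference between the morphine effects. The interaction asks whether the effect of morphine differed between ages. No gene passed by edgeR, with a smallest adjusted p of 0.255 and unadjusted p under 0.05 for 1808 genes against 840 by chance, so that the effects on the 98 genes above were not shown to differ between ages. Egr2 had an interaction of 1.39 on the log2 scale and Sox11 of 0.54, both with adjusted p = 0.255, Arc 0.98 with adjusted p = 0.369 and Fos 0.91 with adjusted p = 0.389. By DESeq2 115 genes passed and by limma-voom 0, and with the myelin marker score in the model 53 passed by edgeR, and without old morphine replicate 1 there was 1. In simulated data for this contrast, 24 of 122 calls by DESeq2 were false, against 5 of 83 by edgeR. Simulated interactions were recovered in 3% of cases at the smallest size (under 1.5-fold), 40.3% at 1.5-fold and 74.2% at 2-fold.

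Of the 98 genes called in old mice, 72 (73.5%, against 55.1% of all genes) had the same sign in young mice and 39 had that sign with an unadjusted p under 0.05, with median changes of 0.41 in old and 0.09 in young mice on the log2 scale. The 98 were chosen for passing in old mice, which raises their median there. Over all genes the changes in the 2 ages had a Pearson r of 0.107 and a Spearman rho of 0.194, where genes are not independent replicates. The changes ran with GC share in opposite directions in the 2 ages (Spearman rho 0.21 in young and -0.47 in old mice), which lowers such correlations. The mean signed change of the 98 genes in young mice was 0.176, the largest of the 20 assignments of the 6 young libraries, with a one-sided exact permutation p of 0.05, the smallest possible. By camera 13 lists differed between the ages, and 0 did with an estimated correlation, where the smallest adjusted p was 0.55. The circadian clock list had a median interaction of 0.22, with 7 of 18 members past the threshold when adjusted over the list alone (adjusted p = 0.000349, and adjusted p = 0.55 with an estimated correlation), and the immediate early genes had 0.24, with 3 of 29 when adjusted over the list alone (adjusted p = 0.000283, and adjusted p = 0.794 with an estimated correlation).

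Age under morphine. The clustered protocadherins were again higher in old mice, here 20 of 57 risen and 1 fallen, and 30 risen and 2 fallen when adjusted over the list alone, with a median of 0.33 (adjusted p = 6.58e-09 by camera, and adjusted p = 0.0438 with an estimated correlation). Pcdhb14 (chromosome 18, 37447656 to 37456350) rose from 17.6 ± 0.708 to 33.5 ± 1.13 CPM, a log2 fold change of 0.93 ± 0.08 with adjusted p = 1e-04. Gpr17 (-0.55), Marcksl1 (-0.93) and Lypd1 (-0.86) fell. Oprk1 (chromosome 1, 5588466 to 5606131), the kappa opioid receptor gene, fell from 2.15 ± 0.376 to 0.681 ± 0.0848 CPM (-1.66 ± 0.47, adjusted p = 0.0422), a change in a gene near 1 CPM, and stood at 0.745 and 0.963 CPM in young and old saline mice. With the GC and length trend described below removed, Oprk1 did not pass (-1.83, adjusted p = 0.11).

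In all, 1621 genes passed, 828 higher and 793 lower, with a median change of 0.31 on the log2 scale. Unadjusted p was under 0.05 for 4431 genes, and 33.1% of genes had no overlap against 10% by chance. These changes moved with the GC share of the genes' transcripts. Over 13399 genes the log2 fold change had a Spearman rho of -0.69 with GC share, against -0.22 under saline, and the median GC share was 41.8% for risen and 57.9% for fallen genes. With a smooth trend of each library on GC share and length removed, an alternative added after the data were seen, 65 genes passed, 58 of them among the 1621. With length-scaled counts, which take in each library's effective lengths, 25 passed. All 3 young morphine libraries had a positive correlation of their deviations with GC share (0.62, 0.28 and 0.36) and all 3 old morphine libraries a negative one (-0.38, -0.32 and -0.66).

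**Figure D3:**
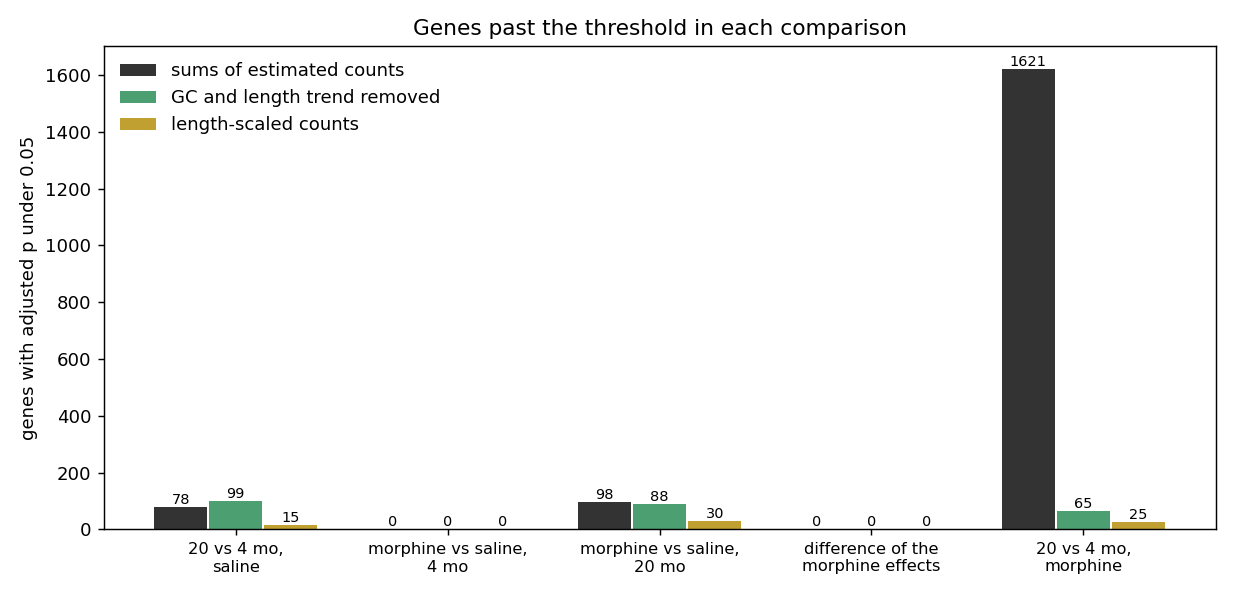
Genes with adjusted p under 0.05 (vertical axis, bars from 0) in the 5 comparisons with the sums of estimated counts, with the GC and length trend removed and with length-scaled counts. For old against young mice under morphine the bars stand at 1621, 65 and 25 genes.

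Besides the genes above, the largest rises under morphine that met the naming rule were Igkc (3.02), Nlrp5-ps (1.75), the pseudogenes Smarca5-ps (1.62) and Znf41-ps (1.4), Casp1 (1.51), Vmn1r90 (1.45), Casp12 (1.4) and Ppl (1.4), and the largest falls included Zxda (-1.59), Klhl1 (-1.51), Cyp26b1 (-0.94), which clears retinoic acid, St8sia2 (-0.88) and Rprm (-0.82). Of these, Smarca5-ps (1.45), Vmn1r90 (1.19), Casp12 (1.07), St8sia2 (-0.86) and Rprm (-0.67) did not pass with the GC and length trend removed, with adjusted p = 0.083, 0.0509, 0.236, 0.0937 and 0.0739; most of each change remained, so the lost calls do not show that the trend accounts for these genes. Of 78 nuclear genes of oxidative phosphorylation, 9 fell and 14 fell when adjusted over the list alone (median -0.11, adjusted p = 1.51e-05, and adjusted p = 0.992 with an estimated correlation), among them Uqcr11 (-0.44) and Cox8a (-0.37). With the trend removed the median was -0.06, and neither gene passed (-0.25 and -0.17, adjusted p = 0.171 and 0.253). Mitochondrially encoded genes had a median of 0.50 (adjusted p = 0.00385, and adjusted p = 0.992 with an estimated correlation), and 0.08 with the GC and length trend removed. Among glutamate and GABA receptor genes, Grin1 (-0.25) and Grm2 (-0.43) fell and Gabra2 rose by 0.27, which turned to -0.12 with the trend removed, where Grin1 and Grm2 did not pass (-0.07 and -0.26, adjusted p = 0.697 and 0.207). Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, fell by 0.37 and the estrogen receptor gene Esr1 by 0.61. With the trend removed neither passed, Slc17a7 at -0.20 (adjusted p = 0.255) and Esr1 at -0.67 (adjusted p = 0.108), a change of Esr1 no smaller than before.

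Genes called with age under saline kept their direction under morphine in 74 of 78 cases (94.9%, against 63.5% of all genes), and 45 were called in both comparisons against 7.5 expected of independent lists. The 1621 genes had the same sign under saline in 1341 cases (82.7%, against the same 63.5%), with a median change of 0.31 under morphine and 0.11 under saline. Both comparisons shared 1 estimate of the spread of each gene. Both also ran with GC share in the same direction (Spearman rho -0.22 under saline and -0.69 under morphine). The 7.5 and 63.5% are therefore not matched baselines for the called genes. The count was 2413 by DESeq2, 1771 by limma-voom and 281 with a score of striatal markers in the model, and without young morphine replicate 1, 2 or 3 it was 384, 770 and 781 and without old morphine replicate 3 it was 493.

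**Figure D4:**
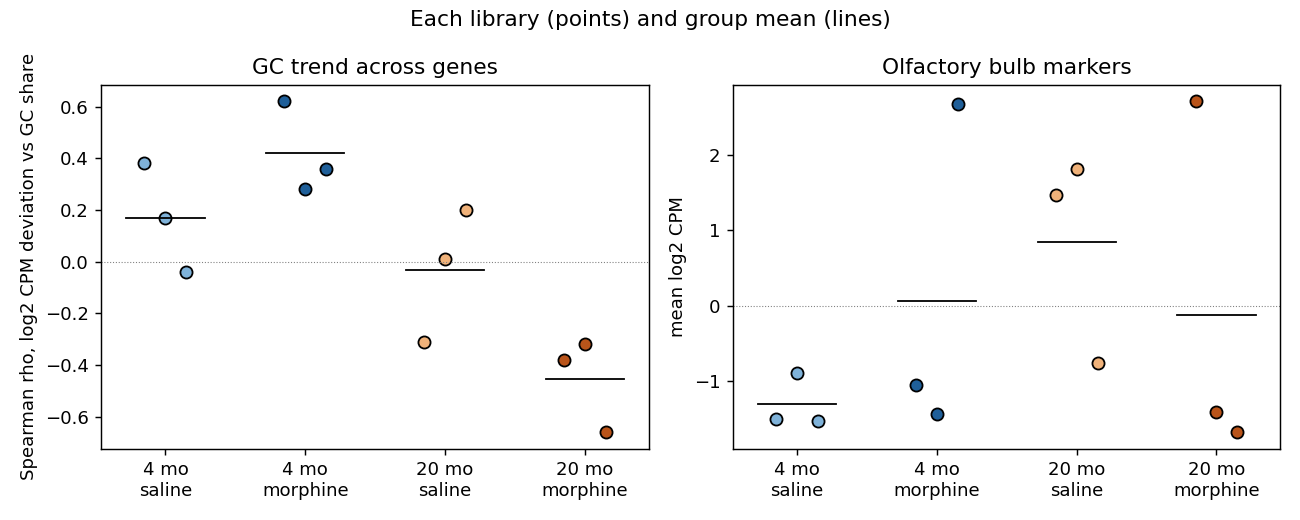
Left, the Spearman rho across genes between each library's deviation in log2 CPM and GC share; right, the mean log2 CPM of 8 olfactory bulb markers; points are libraries and lines are group means. The 4 highest bulb values were 2.71 in old morphine replicate 1, 2.67 in young morphine replicate 3, 1.81 in old saline replicate 2 and 1.47 in old saline replicate 1.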

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

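The GC, depth and single-library tests and the counts over other splits of the samples were chosen after the results they bear on were seen; the exact relabelling of the immediate early genes was set down before its value was known. By camera with the preset correlation, 13 lists had different morphine effects in old and young mice. No such difference held with an estimated correlation, where the smallest adjusted p over the 42 lists was 0.55. Values below are median differences of the log2 fold changes, old minus young.

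The immediate early genes differed by 0.24 (adjusted p = 0.000283). With the GC and length trend removed the median was 0.30, and without young saline replicate 1, the young saline library with the highest mean of the list, it was 0.18, so neither removed most of it. The mean log2 CPM of the list was 3.95 in young and 3.81 in old saline mice, and 4.19 and 4.38 after morphine. Part of the difference thus lies between the saline groups, where the list was lower in old mice (median -0.12, camera adjusted p = 0.00629, and adjusted p = 0.551 with an estimated correlation). By replicate the list stood at 4.16, 3.84 and 3.86 in young saline and 3.87, 3.71 and 3.86 in old saline mice. The higher mean in young saline mice therefore leans on replicate 1. The mean level of the list rose by 0.56 in old and 0.24 in young mice on the log2 scale, and 0.28 of the 400 relabellings within each age gave a difference as large as the observed 0.32 (two-sided exact permutation p = 0.28, where 0.005 is the smallest possible). These relabellings include the drug effect itself, which widens them, so that this p does not decide whether the difference goes beyond the spread between libraries, and a larger response at 20 months stays open.

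The circadian clock genes differed by 0.22 (adjusted p = 0.000349), and mitochondrially encoded genes by 0.63 (adjusted p = 3.99e-05), which was 0.25 with the GC and length trend removed. In old morphine replicates 1, 2 and 3 the mitochondrial list had a mean log2 CPM of 10.79, 10.64 and 11.46, so replicate 3 raised that group's mean. Interferon-stimulated genes differed by -0.43 (adjusted p = 1.2e-05), genes of MHC class I antigen presentation by -0.28 (adjusted p = 0.0161) and reactive astrocyte genes by -0.22 (adjusted p = 0.0386). Mean log2 CPM of the interferon list was 1.87 (young saline), 2.03 (young morphine), 2.30 (old saline) and 2.00 (old morphine). In the same order it was 2.77, 2.81, 3.21 and 3.01 for MHC class I and 1.80, 1.84, 2.35 and 1.99 for reactive astrocytes. Each of these lists stood highest in old saline mice, so the age difference without the drug enters these values. Collagens differed by -0.34 (adjusted p = 0.0119), myelin markers by -0.21 (adjusted p = 0.0161) and blood cell markers by -1.07 (adjusted p = 0.0146). In old morphine replicates 1, 2 and 3 the mean log2 CPM of collagens was 4.74, 4.25 and 3.68. That of blood cell markers was 3.15, 0.72 and 2.75. Replicate 3 thus pulled the collagen mean down, and replicate 2 the blood cell mean. Glucocorticoid-responsive genes differed by -0.15 (adjusted p = 0.0386, and -0.11 with adjusted p = 0.0937 with the trend removed), cholesterol synthesis genes by -0.10 (adjusted p = 0.0161), nuclear genes of oxidative phosphorylation by -0.07 (adjusted p = 0.0386), and glutamate and GABA receptors by 0.09 (adjusted p = 0.024, and 0.05 with adjusted p = 0.272 with the trend removed).

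Many more genes separated the ages under morphine (1621) than under saline (78). The depth of young morphine replicate 2 is argued against, since 1516 genes passed with that library thinned to the median. With each library's trend on GC share and length removed, 65 genes passed under morphine and 99 under saline; the median change of the 1621 genes went from 0.31 to 0.13 while its SE stayed at 0.07, so the calls ended because the changes shrank. A GC trend between the groups, such as a difference in library preparation might leave, is thus a candidate explanation for part of the excess. With the fitted trends alone put on simulated counts without change, 104 genes passed in this comparison. The simulated spread was taken from the data with the trends in it, so 104 does not settle how large that part is. An effect of age under morphine on GC-poor and GC-rich genes cannot be separated from the trend by these tests. The 58 genes called both with and without the trend include Pcdhga2 (0.76, and 0.84 with it removed), Nlrp5-ps (1.75 and 1.72) and Gpr17 (-0.55 and -0.47). For these named genes, removing the fitted trend took away little of the change. Others of the 58 shrank more, such as Znf41-ps from 1.4 to 0.84. Passing both ways therefore does not exclude that the trend holds a share of a change.

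With 3 libraries in each group, 10 splits of 6 libraries are too few for a share under 0.05. Every split but the real one mixes both groups, so a group difference widens the spread within the mixed groups. A GC trend that goes with the groups does the same. Low counts in the mixed splits are therefore not a measure of chance. The real splits gave 78, 0, 98 and 1621 genes for age under saline, morphine in young mice, morphine in old mice and age under morphine, and the highest of the other splits gave 0, 0, 1 and 0; 1, 10, 1 and 1 of the 10 splits gave as many genes as the real one. Where the real count is 0, as in young mice and for the difference of the morphine effects, every split reaches it whatever the data, so that the 10 of 10 splits and the 100 of 100 drawn relabellings say nothing about chance. The highest of the 100 gave 206, in the relabelling that swaps drug and saline at 1 age, which is a structure of the samples, namely the mean morphine effect of both ages.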

How the results depend on the processing

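Directions held in every fit that left out 1 of the 12 libraries for all 78, 98 and 1621 called genes, but counts did not. The called genes were chosen in these same data, so kept signs were nearly fixed in advance and add little support. Where a count moved, the cause was not tested unless stated. Leaving out 1 library gave 15 to 119 genes for age under saline, 0 to 67 for morphine in young mice, 10 to 711 for morphine in old mice, 0 to 1 for the difference of the morphine effects, 384 to 2038 for age under morphine and 47 to 678 for the mean morphine effect. An arm left with 2 libraries shared the spread of the other groups. For named genes, 12287 results under the alternatives stayed on their side of the threshold, 981 lost it and 352 gained it. For lists these were 3060, 183 and 112. A turn of sign was counted only where the result passed in the main fit or in the alternative. The 12287 and 3060 can therefore hold turns of sign among results that passed in neither.

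Age under saline (78 genes) moved to 389 by DESeq2, 341 with the myelin (oligodendrocyte) score, 122 with no filter, 50 with the striatal score, 36 with only the libraries compared (fewer samples), 30 with 1 surrogate variable, 28 with the olfactory bulb score, 24 with that score and the GC offset, and 15 with length-scaled counts. Morphine in young mice (0) moved to 164 by DESeq2, 14 with no filter, 4 with upper-quartile scaling, 2 by limma-voom and 1 with the stricter filter. Morphine in old mice (98) moved to 776 by DESeq2, 160 with protein-coding genes only (fewer genes tested), 30 with length-scaled counts, 28 with the myelin score and 20 with only the libraries compared. The difference of the effects (0) moved to 115 by DESeq2 and 53 with the myelin score. Age under morphine (1621) moved to 281 with the striatal score, 86 with the GC offset and bulb score, 65 with the GC offset and 25 with length-scaled counts. The mean morphine effect (206) moved to 754 by DESeq2, 383 with the GC offset and bulb score, 79 with length-scaled counts, 69 with the striatal score and 0 with the myelin score. Of 67 list calls, 2 held with an estimated correlation.

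Replicate numbers did not pair the libraries: same-numbered libraries had correlations of -0.382 to 0.167, 3 of 18 over 0.1, and 1 of 12 libraries correlated best with its own number. With the replicate block, the counts were 35 for age under saline, 36 for morphine in old mice and 89 for the mean effect, and with the block and the GC offset 38, 45, 20 (age under morphine) and 132.

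Among results that passed in the main fit or in the alternative, signs turned in few cases. For age under morphine, Grk2 went to 0.14 with length-scaled counts, and Gabra2 to -0.12 with the GC offset, -0.11 with the block added and -0.11 with the bulb score added. With the bulb score in the model, medians for age under saline went to -0.42 for bulb markers, as the score itself removes them, and, with the cause not tested, to -0.32 for immature neuron genes and 0.02 for nuclear genes of oxidative phosphorylation, and the difference of the effects to 0.27 for immature neuron genes. Without old morphine replicate 1, nuclear genes of oxidative phosphorylation had a difference of 0. The GC, bulb, thinning and mean-effect alternatives were chosen after seeing the data.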

Other observations

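The tests in this part were chosen after the results were seen, except the second list of olfactory bulb genes, which was written before its levels were looked at. Averaged over both ages, with 6 libraries in each arm, 6 genes of the unfolded protein response rose with morphine and 6 genes that respond to glucocorticoids fell. Of 20 unfolded protein response genes, 6 rose and 0 fell, among them Hspa5, a chaperone of the endoplasmic reticulum (0.41 ± 0.06 on the log2 scale, adjusted p = 0.00393), Xbp1, a transcription factor of that response (0.24 ± 0.04, adjusted p = 0.00713), and Manf (0.29 ± 0.05, adjusted p = 0.0131). The list had camera adjusted p = 2.23e-12, and adjusted p = 0.352 with an estimated correlation, and fry gave adjusted p = 0.00497. Xbp1 stood 0.24 higher with morphine in young and 0.25 higher in old mice.

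Of 26 glucocorticoid-responsive genes, 6 fell and 0 rose in this average: Hif3a (-0.78), Sult1a1 (-0.70), a sulfotransferase, Klf15 (-0.44), Fkbp5 (-0.40), the kinase gene Sgk1 (-0.27) and the connexin gene Gjb6 (-0.35), with adjusted p = 0.546 for the list with an estimated correlation. Of 29 immediate early genes, 12 rose and 0 fell (camera adjusted p = 3.59e-11, and adjusted p = 0.546 with an estimated correlation). Of 19 astrocyte markers, F3, Gja1 and Gjb6, which is also in the glucocorticoid list, fell, with a median of -0.17 (camera adjusted p = 7.54e-07, and adjusted p = 0.631 with an estimated correlation). Markers of meningeal fibroblasts had a median of -0.60 with 0 of 16 past the threshold (camera adjusted p = 1.13e-07, and adjusted p = 0.647 with an estimated correlation). All 16 stood lower with morphine in each age, but they moved together (estimated correlation 0.878) and are not separate results. In young mice the groups overlapped, with mean log2 CPM of 3.88, 4.62 and 4.45 after saline and 4.19, 3.22 and 4.02 after morphine. In old mice the values were 4.40, 4.63 and 4.77 after saline and 4.39, 3.96 and 3.21 after morphine. The cause was not tested. Oprd1, the delta opioid receptor gene (chromosome 4, 132110726 to 132144486), rose by 0.26 ± 0.06 (adjusted p = 0.0378), and Slc2a1, the glucose transporter of brain vessels, fell by 0.37. These genes were named after their values were seen.

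The finding of 0 genes in young and 98 in old mice may reflect a response shared by both ages that 3 libraries against 3 did not carry past the threshold in young mice. The mean effect of both ages called 206 genes, 136 higher and 70 lower, of which 62 were also called in old mice alone and 39 had an interaction with an unadjusted p under 0.05. Of the 98 genes called in old mice, 72 had the same sign in young mice, with median changes of 0.41 in old and 0.09 in young mice. These were chosen for passing in old mice, which raises their median there. For the 206 genes the median sizes were 0.35 in old and 0.29 in young mice, and 205 had the same sign in both ages. They were chosen on the mean of both ages, which favours genes that moved alike. Neither set decides between the ages, so a smaller response in young mice stays open too. The mean effect was looked at because its arrangement had the most genes of the 100 drawn relabellings within each age. Of the 100, 1, that arrangement itself, gave 206 and the highest of the others 11, which restates how it was found and does not exclude chance. With the GC and length trend removed 252 genes passed, 183 of them shared. Leaving out 1 library gave 421 and 678 genes without young saline replicate 1 and old saline replicate 1, 47 and 69 without young saline replicates 3 and 2, 110, 66 and 62 without young morphine replicates 1, 2 and 3, 76 and 62 without old saline replicates 2 and 3, and 94 and 87 without old morphine replicates 2 and 3.

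Myelin content of the dissection could be another source of that shared response, and it stays open. Myelin markers averaged 3.80 and 4.21 log2 CPM in young saline and young morphine mice and 4.08 and 4.26 in old ones, so the score moved with the drug. With the score in the model 0 of the 206 genes passed (smallest adjusted p = 0.108), while the median change went from 0.32 to 0.23 and its SE from 0.06 to 0.08, so the calls ended through both smaller changes and a larger error; all 206 kept their sign and 170 had an unadjusted p under 0.05. The median of the immediate early genes went from 0.38 to 0.20 and that of the unfolded protein response genes from 0.18 to 0.13. This test was the last of those tried for the morphine response and its bound was set when the count of 0 was already known; because the score differs between drug and saline, a share of the response due to tissue makeup and a response of the drug cannot be told apart here.

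Olfactory bulb markers were high in 4 libraries of 3 groups: old morphine replicate 1 (mean log2 CPM 2.71), young morphine replicate 3 (2.67), old saline replicate 2 (1.81) and old saline replicate 1 (1.47), against -1.68 to -0.76 in the other 8. Olfactory bulb tissue in the dissection is a candidate source: the 4 libraries highest for a second list of bulb genes were the same 4 (3.61, 3.48, 2.86 and 2.79), although the next, young morphine replicate 1, stood close at 2.71 and Slc17a6 of that list was lower in old saline replicate 2 (6.28 CPM) than in old morphine replicate 3 (12.6 CPM). Cdhr1, a cadherin of bulb output neurons, stood at 46.9 and 48.2 CPM in young morphine replicate 3 and old morphine replicate 1 and at 24.9 and 24.1 CPM in old saline replicates 2 and 1, and at 3.25 to 5.53 CPM elsewhere, and Th at 12.8, 9.87, 6.03 and 4.28 CPM. Library depth is argued against, as 1 of the 4 was among the 4 deepest and 2 were among the 4 shallowest libraries. Of the 6 measured genes of the second list, 5 reached 1 CPM in all 12 libraries and 1 (Sp8) is also in the list of immature neuron genes, and no biological explanation was tested.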
